A study of Mus musculus with 10 samples.

How the data were processed

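RNA was measured in basophils sorted by flow cytometry from the spleens of female mice on a C57BL/6 background, in 10 libraries and 4 groups. The groups were taken from the library titles, which combine 2 letters for the Cre state (mCre or pCre) with the infection state, and held 3 mCre naive, 3 pCre naive, 2 mCre infected and 2 pCre infected libraries. Directional libraries were prepared from 25 ng of total RNA after polyA selection, per the labels' protocols. Nothing in the labels says whether the libraries of a group came from separate mice, so the q-values measure the spread between these libraries, which may be technical.

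Reads were quantified with kallisto 0.43.0, a tool that assigns reads to transcripts without aligning them to the genome, and compared with sleuth, per the submitters' processing notes, which also name the mm10 build. The sleuth version, the transcript annotation, the model and the filters are not given in the sources used here. The values used were those of 1 table, which holds for each transcript a q-value and an effect b in each of 4 comparisons: pCre against mCre in naive mice, pCre against mCre in infected mice, infected against naive in mCre, and infected against naive in pCre. The q-values deposited by the authors are p-values adjusted for the number of transcripts tested. The effects b deposited by the authors are taken as natural log ratios, the scale on which sleuth reports by default, and as pCre minus mCre or infected minus naive, the order that default factor levels would give. Neither the log base nor the sign is stated in the table or the labels. The 4 columns were checked against each other: the difference of the Cre effects equals the difference of the infection effects with a median absolute residual of 0.0065 over 30496 transcripts, against 0.35 to 0.53 when any 1 column is reversed. The columns thus share 1 orientation, and reversing all 4 together would exchange higher and lower throughout. No values per library were used here, so the depth of each library is unknown, and the limma and edgeR fits planned before the data were examined gave way to the planned fallback, the authors' q-values under 0.05.

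The table lists 88198 transcripts, of which 39013 were tested in at least 1 comparison and 30492 in all 4; the other 49185 have no q-value. Transcript identifiers were matched to GENCODE M21, an annotation of GRCm38, the assembly that mm10 names, and 97.6% were found there. Symbols in the table were used, except that 1627 transcripts without a symbol and 76 whose symbols had turned into dates took the annotation's symbol where it had one. Coordinates are those of GENCODE M21. In each comparison most transcripts share 1 q-value just below 1 (97.1%, 85.1%, 96.5% and 99.1% of those tested, in the order given above), so counts at an unadjusted p cannot be given.

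Standard errors were recovered, by a method chosen after the table was seen. The Benjamini-Hochberg adjustment was inverted from the ranks of the q-values, giving the lowest and highest p each q allows, and the error is the size of b divided by the normal quantile of p, which assumes that the q-values come from a two-sided Wald test. An error was used only where its highest and lowest possible values differed by less than a factor of 1.1. The difference between the infection effects in pCre and mCre (the interaction) was tested with these errors. The Cre effects served where the infection effects lacked an error. Each of these pairs compares separate libraries. Averages of the infection effects and of the Cre effects were tested in the same way, all with Benjamini-Hochberg adjustment over every transcript tested in the pair, where those without a recoverable error were kept in the count as not passing. For the interaction both pairs were counted, since either could supply the p-value. This adjustment replaced one over the transcripts with recoverable errors alone, after its counts were seen. Only transcripts with a recoverable error in both members of a pair can enter, which favours transcripts with small p-values in both. Overlaps expected without any effect came from 100 simulations.

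Before the data were examined, 18 lists of pathway genes and 11 lists of cell type markers were fixed. A gene's value was the median b of its tested APPRIS principal transcripts, the annotation's main isoforms, or of all tested transcripts where no principal one was tested; this choice was made after the table was seen. For lists with at least 5 measured genes, the median was given with a 95% bootstrap interval over genes from 10000 draws. The number of genes with a called transcript was compared with all tested genes by a one-sided Fisher's exact test, adjusted over the 114 tests of lists and comparisons. Genes are not independent replicates, so these intervals and tests describe the lists within these libraries. Counts adjusted over the list alone used the highest p each q allows and are lower limits. The planned camera test needs values per library and was not run.

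Genes named by rule, fixed before the data were examined, are up to 8 called transcripts with the largest rise and up to 8 with the largest fall per comparison, the 10 called list members with the smallest q, and 11 genes named irrespective of the test. The rule's minimum expression and its condition of no overlap between libraries could not be applied. Predicted genes were counted and not named. Alternatives were q-values under 0.01 and 0.1, a change of at least 2-fold, genes counted once, and, chosen after seeing the data, only principal transcripts, only transcripts tested in all 4 comparisons, and leaving out transcripts with b beyond 3 in either direction. The calculations were tested on simulated data, in tables with 200 changed transcripts each. Of the 2-fold changes, between 39.1% (infection in pCre) and 58.0% (infection in mCre) were called, and of the 4-fold changes between 89.9% (Cre in naive) and 95.2% (infection in pCre), over 33254 to 35496 transcripts in the comparisons named. The simulated standard errors were drawn from the same distribution for all 4 comparisons and not from these libraries. The rates therefore check the calculations and do not measure or rank the sensitivity of the real comparisons. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

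The assignment of reads between near-identical genes is uncertain in transcript quantification. This concerns the tryptases Tpsb2 and Tpsab1, the mast cell proteases Mcpt1, Mcpt2 and Mcpt4, the globins, the pancreatic trypsins and the ribosomal proteins with their pseudogenes.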

Results

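The transcriptome of splenic basophils, rare granulocytes that release histamine and type 2 cytokines, was measured in naive mice and in mice 14 days after infection with 200 eggs of Trichuris muris, a whipworm of the large intestine. All mice received complexes of interleukin-3 on days 5 and 2 before harvest, which expands basophils. They carried the DNMAML allele, a dominant-negative form of the Notch coactivator Mastermind-like. It blocks Notch-dependent transcription once Cre has acted. A Cre recombinase under the basophil gene Mcpt8 was carried in addition, by all mice under the sample labels but not by all under the growth protocol. Whether 1 of the 2 Cre states is a control without Notch inhibition is therefore not settled. The 2 Cre states are called mCre and pCre after the titles. The labels do not settle their genotypes: the sample labels give 1 Cre allele for mCre and 2 for pCre, whereas the growth protocol gives 1 or none. The libraries numbered 3 mCre naive, 3 pCre naive, 2 mCre infected and 2 pCre infected. All effects are b, the natural log ratio, in the authors' deposited table, positive where pCre or the infected mice were higher under the default orientation, which the labels do not state.

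Mcpt8, the basophil protease gene for which the Cre is named (ENSMUST00000015594, chromosome 14, 56082166 to 56085197, minus strand, GRCm38), did not pass the test between pCre and mCre in naive mice in the authors' deposited table (b = -0.017). It fell with infection in mCre (b = -0.69, q = 0.0289) and was 4.75-fold higher in pCre than in mCre after infection (b = 1.56, q = 7.92e-23) in the authors' deposited table. With infection in pCre it had b = 0.88 and did not pass there (q = 0.233). Maml1, the mouse gene of the Mastermind-like protein, has 2 tested transcripts on chromosome 11. In the authors' deposited table the principal one (ENSMUST00000059458, 50255634 to 50292311) was lower in pCre infected basophils (b = -0.54, q = 0.000303), and the shorter one (ENSMUST00000135868, 50255634 to 50291804) was higher there (b = 7.60, q = 4.09e-38). In naive mice neither Maml1 transcript passed, and the principal one had b = -0.026 in the authors' deposited table. The labels do not say which of these transcripts the DNMAML allele could contribute to, so the values do not check the genotype.

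The authors' deposited table called 102 transcripts for infection in mCre, 66 of them higher and 36 lower, against 22 for infection in pCre, 7 higher and 15 lower, at q under 0.05. Between pCre and mCre it called 55 transcripts in naive mice, 22 higher and 33 lower, and 207 in infected mice, 101 higher and 106 lower. These calls belonged to 96, 22, 52 and 193 genes, in that order. Part of each count came from transcripts with b beyond 3 in either direction, which numbered 25, 6, 22 and 68. Their recovered standard errors had medians of 1.13 to 1.34, against 0.117 to 0.189 for the other calls. For infection in mCre 24 of the 25 were lower, and for infection in pCre all 6 were. Within b of 3, the calls were 65 higher and 12 lower for infection in mCre, and 7 higher and 9 lower for infection in pCre.

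**Figure D1:**
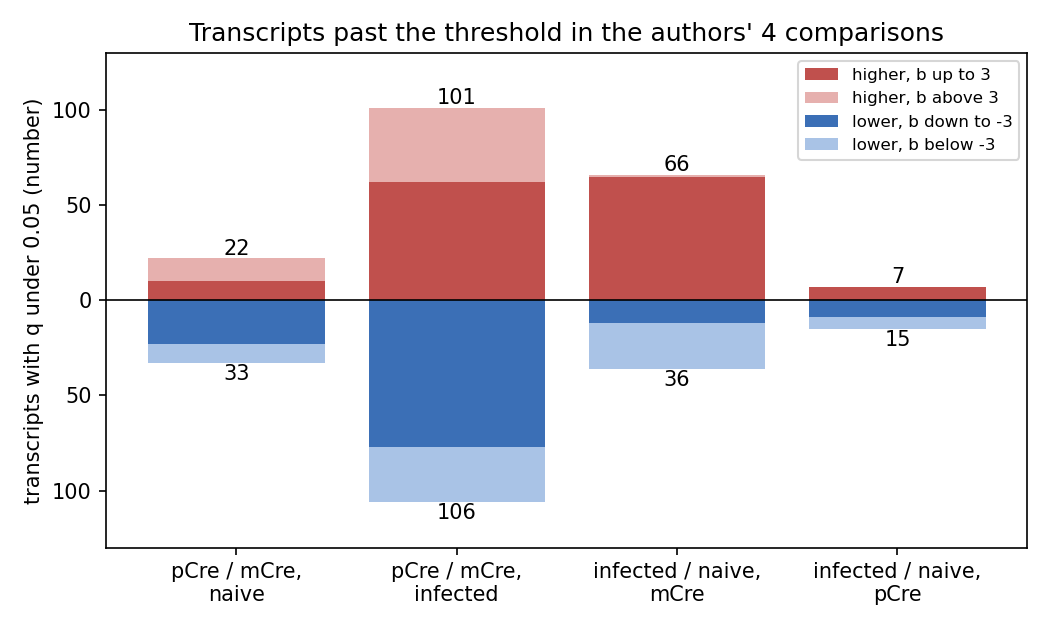
Number of transcripts with q under 0.05 in each of the authors' 4 comparisons (x axis), with higher transcripts above and lower ones below 0 on the y axis. Dark bars hold transcripts with b within 3 of 0 and light bars those beyond; pCre against mCre in infected mice has the tallest bars, with 101 higher and 106 lower.

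The first comparison asks what infection changed in mCre basophils. Genes of mast cell proteases and of mast cell development rose together. In the authors' deposited table the tryptase gene Tpsb2 (chromosome 17, 25366550 to 25368094) rose 11.5-fold (b = 2.45, q = 1.99e-23), the chymase-type protease genes Mcpt1 and Mcpt4 rose 8.35-fold and 6.94-fold (q = 0.000152 and 0.00979), and Mitf, the gene of a transcription factor of mast cells and melanocytes, rose 6.88-fold (q = 6.68e-09). A transcript of Kit, the stem cell factor receptor gene, rose 4.76-fold in the authors' deposited table (q = 2.56e-08), while the principal Kit transcript, with b = 1.49, did not pass. Hes1, a target gene of Notch (chromosome 16, 30065340 to 30067796), rose 5.90-fold (q = 1.99e-14) in the authors' deposited table. Of the fixed list of mast cell markers, 4 of 7 measured genes had a called transcript, all higher, and 8 of 9 transcripts passed when adjusted over the list alone. The list had a median b of 1.94 (95% bootstrap interval 1.62 to 2.45) and held more called genes than all tested genes (one-sided Fisher's exact test, adjusted p = 3.53e-06).

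Some of the other genes called for infection in mCre were members of fixed lists. The granule and protease list had 5 called genes among 25 measured, Tpsb2, Mcpt1, Mcpt4 and Gzmb higher and Mcpt8 lower (one-sided Fisher's exact test, adjusted p = 2.55e-05), and 8 of its transcripts passed when adjusted over the list alone. Its median b was 0.068 (-0.18 to 0.81), with 14 genes positive. Among basophil cytokines and mediators, 3 of 24 measured genes rose: in the authors' deposited table Hpgds, the prostaglandin D synthase gene, rose 4.46-fold (q = 0.0138), Gzmb, which encodes granzyme B, 4.14-fold (q = 1.59e-06) and Tnf 3.28-fold (q = 0.00129). The one-sided Fisher's exact test gave an adjusted p of 0.0101 for that list, and 6 of its transcripts passed when adjusted over the list alone. The Notch target list held 2 called genes of 11, Hes1 and the cell cycle inhibitor gene Cdkn1a, both higher (one-sided Fisher's exact test, adjusted p = 0.0319), and 3 transcripts passed when adjusted over the list alone. Its median b was 0.59 (0.055 to 1.14), with 9 genes positive. Cd34 (b = 1.48) and the integrin gene Itga4 (b = 1.04) rose among the 31 measured migration and adhesion genes in the authors' deposited table, where 3 transcripts passed when adjusted over the list alone. That list did not hold more calls than all genes (one-sided Fisher's exact test, adjusted p = 0.144), and its median b was -0.086 (-0.12 to -0.050), with 22 genes negative. The immediate early list, genes that respond within minutes to stimulation, had called transcripts of Dusp2 (b = 1.21) and Tnfaip3 (b = 0.48) in the authors' deposited table. Its median b was 0.63 (0.58 to 0.88), with 31 of 32 genes positive and 14 transcripts passing when adjusted over the list alone, but it did not hold more calls than all genes (one-sided Fisher's exact test, adjusted p = 0.144).

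Further transcripts that rose in the authors' deposited table were those of Rps12 (b = 6.47), B3galt5 (2.54), Hic1 (1.95) and the drug transporter gene Abcb1a (1.93). The largest falls with infection in mCre in the authors' deposited table were those of transcripts of Cpeb2 (b = -6.90), Disp1 (-6.67), Tmbim6 (-6.02), Kat6b (-5.91), Ift80 (-5.70), Fmo5 (-5.67), Matr3 (-5.49) and Atad5 (-5.44). Beside these changes, the 13 measured B cell markers were all positive, with a median b of 1.19 (1.09 to 1.36), and the plasma cell markers had a median of 1.15 (0.79 to 1.78). The neutrophil markers had a median of 0.37 (0.12 to 0.80), and the pancreatic acinar genes, a list added after 2 of its kind were seen, one of 2.99 (1.89 to 3.47), positive in all 13 measured genes, with 12 transcripts passing when adjusted over the list alone. No B cell, plasma cell, neutrophil or listed acinar transcript reached q under 0.05 in the authors' deposited table. The erythroid markers had a median b of -0.034 (-0.21 to 0.053), and the intervals of the T cell, macrophage and monocyte, dendritic cell, eosinophil and platelet markers also contained 0. The comparison rests on 2 infected libraries, which are also the reference of the Cre comparison in infected mice.

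The Cre comparison in infected mice asks how basophils of the 2 Cre states differed on day 14. Mast cell genes were lower in pCre. In the authors' deposited table Mrgprb1, a mast cell receptor gene, was 16.8-fold lower (b = -2.82, q = 0.000888), Tpsb2 13.7-fold (b = -2.62, q = 9.49e-09), Mcpt4 6.38-fold (b = -1.85, q = 2.81e-37) and the chymase gene Cma1 6.00-fold (b = -1.79, q = 1.23e-05). Mitf (b = -1.68), Hes1 (b = -1.65, q = 4e-10), a transcript of Kit (b = -1.47), Mcpt2 (b = -1.46) and Mcpt1 (b = -1.45) were also lower in the authors' deposited table, as was Ahr, the aryl hydrocarbon receptor gene (b = -1.32, q = 6.67e-12). Of 8 measured mast cell markers, 6 had called transcripts, all lower, and 8 of 11 transcripts passed when adjusted over the list alone. The list median was -1.83 (-2.62 to -1.68), and the list held more called genes than all tested genes (one-sided Fisher's exact test, adjusted p = 2.38e-08). The Notch target list had 2 called genes of 11, Hes1 and Cdkn1a, both lower, and did not pass (one-sided Fisher's exact test, adjusted p = 0.0772), with 4 transcripts passing when adjusted over the list alone. Its median b was -0.46 (-0.77 to -0.096), with 9 genes negative. Between pCre and mCre in naive mice the Notch target median was 0.21 (-0.071 to 0.75), with 8 of 11 measured genes positive. The list of basophil cytokines and mediators had 1 called gene of 27, Hpgds, which was lower, and did not hold more calls than all genes. The median b of that list was -0.37 (-0.73 to -0.040), with 21 genes negative, and 8 transcripts passed when adjusted over the list alone.

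Cell division genes were higher in pCre than in mCre after infection. Of the 40 measured proliferation genes, 8 were called, all higher: in the authors' deposited table Birc5, the survivin gene, had b = 0.86, the mitotic checkpoint gene Bub1 0.85, the cyclin gene Ccnb1 0.83 and Mki67, which marks dividing cells, 0.60, alongside Cdca8, Cenpf, Kif11 and Ube2c. When adjusted over the list alone, 18 transcripts passed. The list median b was 0.57 (0.48 to 0.65), 38 of the 40 genes were positive, and the one-sided Fisher's exact test gave an adjusted p of 3.53e-06. Of the 29 ribosomal protein genes measured, 4 had called transcripts, all higher (one-sided Fisher's exact test, adjusted p = 0.0101), and 4 transcripts passed when adjusted over the list alone. In the authors' deposited table these ranged from Rpl7 (b = 0.79) to Rps14 (b = 7.12) and Rps2 (b = 6.25). None of the 4 is a principal transcript, and the principal ones of these genes had values from -0.12 for Rpl7 to 0.18 for Rps2. Rnase12 was 3.64-fold higher in the authors' deposited table (b = 1.29). The immediate early list had no transcript with q under 0.05 in sleuth, with 0 passing when adjusted over the list alone, and each of its 32 measured genes was negative, with a median b of -0.88 (-1.44 to -0.66).

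Among basophil identity genes, 3 of 22 had called transcripts in this comparison, Mcpt8 higher and transcripts of Hdc, the histamine synthesis gene, and Il18rap, an interleukin-18 receptor subunit gene, lower (one-sided Fisher's exact test, adjusted p = 0.0370), and 7 transcripts passed when adjusted over the list alone. The called transcripts of Hdc and Il18rap are not principal ones, whose values were 0.26 for Hdc, in the other direction, and -0.038 for Il18rap. The list's median b was 0.096 (-0.024 to 0.20). The granule list had 6 called genes of 26, 1 higher and 5 lower (one-sided Fisher's exact test, adjusted p = 3.16e-05), and 9 transcripts passed when adjusted over the list alone. The median b of the granule list was 0.19 (-0.44 to 0.44), with 16 of the 26 genes positive. Transcripts with the largest rises in the authors' deposited table were those of Tmsb4x (b = 10.6), Maml1, Tle3 (7.15), C5ar1 (7.13), Rps14, Tmbim6 (6.99), Slc35c2 (6.87) and Ptk2b (6.73). The largest falls in the authors' deposited table were those of Pik3cd (b = -6.85), Ptbp3 (-6.81), Xpo7 (-6.49), Mical1 (-6.42), Slu7 (-6.22), L1cam (-6.11), Ciz1 (-6.00) and Cr2 (-5.90). Beside these changes, the B cell markers had a median b of -0.49 (-0.57 to -0.22) and the erythroid markers of -0.70 (-0.93 to -0.17). The plasma cell markers had one of -0.36 (-1.57 to -0.15), the platelet markers of -0.090 (-2.00 to -0.023) and the neutrophil markers of 0.32 (0.00089 to 0.64). The pancreatic acinar list had one of -0.88 (-1.10 to -0.42), negative in all 21 measured genes, with 0 transcripts passing when adjusted over the list alone.

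Transcripts lower in pCre after infection were compared with those that rose with infection in mCre. Of 102 lower and 66 risen transcripts tested in both comparisons, 29 were in both, against 0.207 for independent lists and 7.97 for simulated comparisons without any effect that share the mCre infected libraries. With 2 libraries in that group the controls cannot be split, and part of the excess may come from sharing them.

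**Figure D2:**
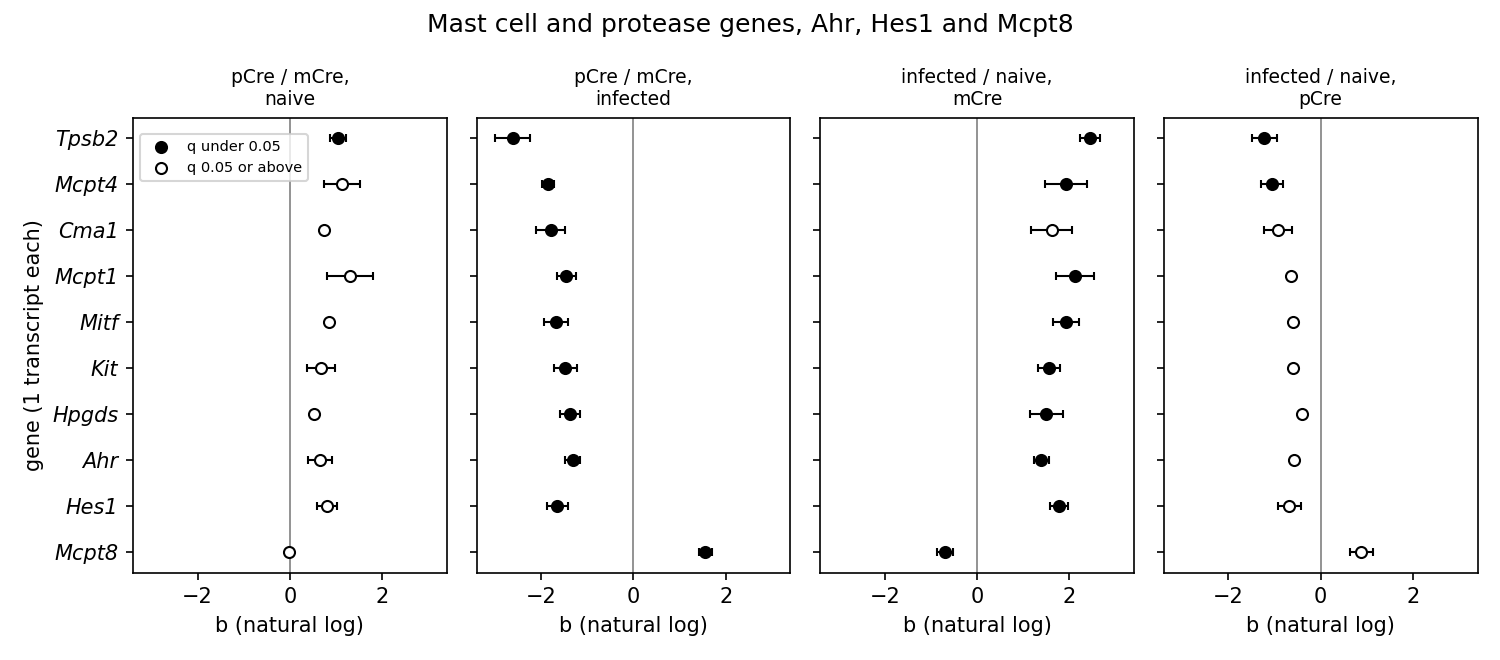
Effect b (natural log ratio, x axis) of 1 transcript each of 10 genes (y axis) in the authors' 4 comparisons, picked after their values were seen as each gene's transcript with the most comparisons past the threshold; bars are 1 recovered standard error, left out where none could be recovered, and filled points have q under 0.05. Tpsb2 has b of 1.05, -2.62, 2.45 and -1.22 from left to right, and Mcpt8 moves against the mast cell genes in the infected and mCre panels.

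Infection in pCre basophils gave fewer calls, and mast cell proteases moved the other way. The reference here is the pCre naive libraries, which also enter the Cre comparison in naive mice. Against mCre naive, pCre naive had b of 1.05 for Tpsb2, which passed, and of 1.13 for Mcpt4, which did not. Relative to mCre naive, the pCre infected values were -0.17 for Tpsb2 and 0.081 for Mcpt4. Whether high pCre naive libraries or infection gave the falls below was not tested, since no values per library were used. Tpsb2 fell 3.39-fold (b = -1.22, q = 0.0164) and Mcpt4 fell 2.87-fold (b = -1.05, q = 0.0373) in the authors' deposited table. Transcripts of Cish, a feedback gene of cytokine signalling (b = -0.79), of the immediate early gene Egr3 (b = -0.76), and of the platelet integrin gene Itga2b (b = -0.61) were lower in the authors' deposited table. The principal Cish and Itga2b transcripts had b of -0.16 and -0.11 and did not pass there. Higher transcripts in the authors' deposited table were those of Mark2 (b = 2.16), Rnase12 (0.92, a 2.51-fold rise), Actb (0.62), Gda (0.49), Dynlt1b (0.44), Pdzd4 (0.39) and the interferon-induced membrane protein gene Ifitm2 (0.38). The called Actb transcript is not the principal one, which had b = 0.11. Further falls in the authors' deposited table were those of transcripts of Msh3 (b = -5.28), Arhgap39 (-5.28), Ikbke (-4.95), Atf7ip (-4.55) and Tnpo2 (-3.61). The mast cell list had 2 called genes of 7, both lower, 3 transcripts passing when adjusted over the list alone, and a median b of -0.93 (-1.05 to -0.60). The one-sided Fisher's exact test gave an adjusted p of 0.00108 for this list and of 0.0101 for the granule list, whose called genes were also Tpsb2 and Mcpt4 and of whose transcripts 4 passed when adjusted over the list alone. The granule list as a whole did not fall: 17 of its 25 measured genes were positive, with a median b of 0.22 (-0.10 to 0.39). The immediate early list, with Egr3 called, 1 transcript passing when adjusted over the list alone and 29 of 31 genes negative, had a median b of -0.48 (-0.76 to -0.30; one-sided Fisher's exact test, adjusted p = 0.265). Beside these changes, the B cell markers had a median b of -0.23 (-0.42 to -0.18), the T cell markers of -0.26 (-0.46 to -0.078) and the erythroid markers of -0.49 (-0.66 to -0.058), while the plasma cell markers had one of 0.42 (0.14 to 2.10), positive in all 6 genes. No transcript of these 4 lists was called.

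In naive mice the Cre states differed in few genes. Tpsb2 was 2.84-fold higher in pCre (b = 1.05, q = 1.69e-06) in the authors' deposited table, and the pancreatic enzyme genes Ctrb1 (b = 3.42, q = 0.0126) and Cela2a (b = 3.74, q = 0.0372), named after their values were seen, were higher too. Transcripts of the interleukin-18 receptor genes Il18r1 (b = -0.66) and Il18rap (b = -0.50) were lower in the authors' deposited table, both of them other transcripts than the principal ones, which had b of -0.048 and -0.071. These 2 genes were the called members of the Toll-like and alarmin receptor list, which did not pass (one-sided Fisher's exact test, adjusted p = 0.0539) and had 2 transcripts passing when adjusted over the list alone. Transcripts of Gbp3 (b = 5.11) and Pik3cd (b = -5.87) were the other list members called in the authors' deposited table. The largest falls in the authors' deposited table included transcripts of Lcp1 (b = -8.61), Reps2 (-6.16), Padi2 (-6.07), Ptbp3 (-5.98), Laptm5 (-5.63), Kif5b (-5.52) and Akt1 (-5.42). The largest rises in the authors' deposited table were those of Tiam1 (b = 6.65), Mob1a (6.07), Mysm1 (5.71), Cux1 (5.60), Tcn2 (5.59), Tnfaip1 (5.43), Dnajc6 (5.14) and Sh2d5 (5.14). Only 15 of the 55 called transcripts were principal ones. The immediate early list had a median b of 0.29 (0.21 to 0.40), positive in 29 of 32 genes, with no called transcript and 0 passing when adjusted over the list alone. The Notch target list had no called transcript, and 2 passed when adjusted over the list alone. Its median b was 0.21 (-0.071 to 0.75), with 8 genes positive, among them Hes1 (0.80) and Cdkn1a (0.76), and 3 negative. Beside these, the B cell markers had a median b of 0.95 (0.90 to 1.07), the T cell markers of 0.59 (0.54 to 0.82) and the neutrophil markers of 0.47 (0.047 to 0.83), with no called transcript. When adjusted over the list alone, 1 T cell transcript passed. The mast cell list, with Tpsb2 called and 2 transcripts passing when adjusted over the list alone, had a median of 1.05 (0.75 to 1.13) and did not pass (one-sided Fisher's exact test, adjusted p = 0.162). The pancreatic acinar list, added after Ctrb1 and Cela2a were seen, had one of 2.14 (1.81 to 2.44), positive in all 17 measured genes. It had no called transcript, and 13 passed when adjusted over the list alone.

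**Figure D3:**
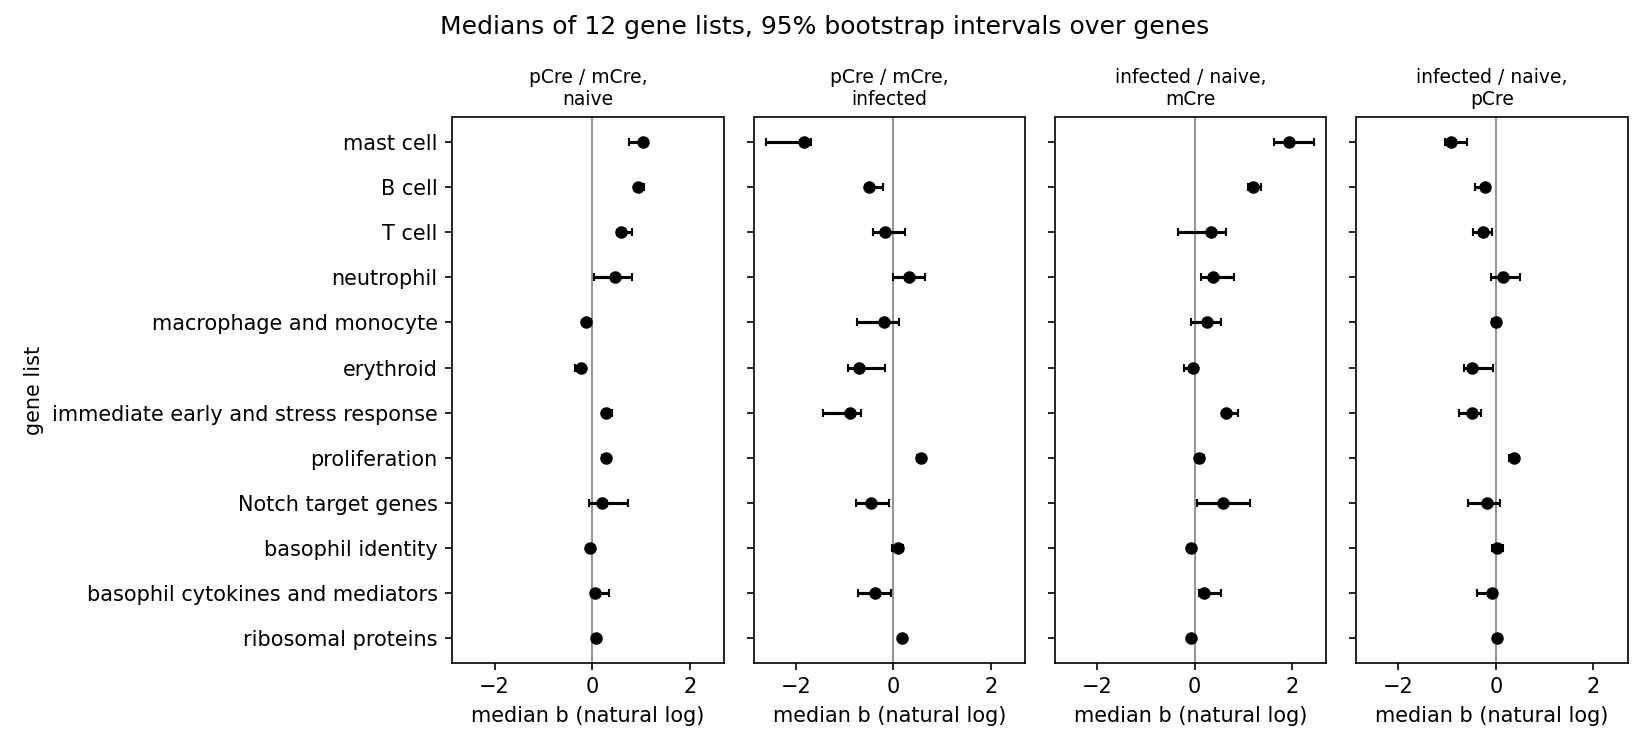
Median b (natural log ratio, x axis) over the measured genes of 12 lists (y axis), picked from the fixed lists after their values were seen, in the authors' 4 comparisons, with 95% bootstrap intervals over genes. The mast cell list has medians of 1.05, -1.83, 1.94 and -0.93 from left to right.

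The design also asks whether infection acted differently in the 2 Cre states. Errors were recoverable in a pair of comparisons for 281 transcripts. Adjusted over the 63620 differences of the infection effects and of the Cre effects in all tested transcripts, 33 passed for the difference between the infection effects, 25 lower and 8 higher in pCre; 18 of these came from the infection effects and the others from the Cre effects, and the infection effects alone also gave 18. Effects of opposite sign in the pair compared were found in 109 of the 281 and in all 33 that passed, and since only transcripts with small p-values in both comparisons could enter, the count says little about differences between effects of the same sign. Tpsb2 had the smallest adjusted p: its infection effect was lower in pCre by b = -3.67 ± 0.35 (SE), with an adjusted p of 3.73e-21 from the difference test on sleuth's values. Hes1 (-2.45 ± 0.32), Mcpt4 (-2.99 ± 0.52) and a transcript of Kit (-2.16 ± 0.39) differed in the same direction, and Mcpt8 (1.57 ± 0.31) in the other. Of the 66 transcripts that rose with infection in mCre, 54 had negative b with infection in pCre, a comparison without shared libraries, where their median b was -0.33. High values in the pCre naive libraries, the reference in pCre, would also give negative b. The transcripts that fell with infection in mCre showed no such reversal: of the 29 that were also tested in pCre, 16 had negative and 13 positive b there. The 2 sets are unlike, since 65 of the 66 risen transcripts had b within 3 in mCre, against 12 of these 29. Those 12 had 6 negative and 6 positive b in pCre, with a median of 0.061. The average infection effect, adjusted over 30835 transcripts, passed in 3, which were transcripts of Rps12 (average b = 5.94), Ly6c2 (-4.15) and the cell cycle inhibitor gene Cdkn1b (-0.39 ± 0.070). The average Cre effect, adjusted over 32785, passed in 29, 5 higher and 24 lower in pCre, with the smallest adjusted p for transcripts of Pik3cd (average b = -6.36 ± 0.83) and Il18rap (-0.56 ± 0.086), neither of them principal ones. All of these had the same sign in both comparisons. Transcripts without a recoverable error could not pass, so these counts are lower limits.

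Genes of type 2 cytokines and of the Notch pathway that were to be named irrespective of the test mostly did not pass. In the authors' deposited table the principal Il4 transcript had b of 0.31 and 0.32 for infection in mCre and pCre, Il13 0.48 and -0.85, and Il6 0.54 and -0.056, with q of 0.0715 or more. Between pCre and mCre after infection the authors' deposited table gave Il4 -0.31, Il13 -0.73 and Il6 -0.29, and in naive mice -0.33, 0.60 and 0.30. Notch1 and Notch2 lay between -0.17 and 0.093 in all 4 comparisons of the authors' deposited table for their principal transcripts. The Notch feedback gene Nrarp had b of 0.64 between pCre and mCre after infection (q = 0.105) and Dtx1 of -0.46 in the authors' deposited table. The principal Gata2 transcript ENSMUST00000015197, of a basophil and mast cell transcription factor gene, had b between -0.049 and 0.17 in the authors' deposited table, and the other principal transcript of Gata2 had b from -0.70 to 3.19 without passing.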

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

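The test of the pancreatic genes was fixed before their values were seen; the tests of mast cell share, of other cell types, of Mcpt8 dilution and of other transcripts were chosen only after related values had been seen, and so were the tests of the difference between infection effects.

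The infection effect differed between pCre and mCre for 13 transcripts of listed genes, by a test of the difference itself. The difference was negative, lower in pCre, for Tpsb2 (-3.67), Hes1 (-2.45), Mcpt4 (-2.99), Kit (-2.16), Mcpt1 (-2.76), Cma1 (-2.55), Egr3 (-2.53), Mcpt2 (-2.67), Cdkn1a (-1.79), Dusp2 (-1.86) and a transcript of Hdc (-1.20). It was positive for Mcpt8 (1.57) and for a transcript of the ribosomal protein gene Rpl7 (0.93). The adjusted p was 0.0436 or less. The Hdc and Rpl7 transcripts are not principal ones, and the principal ones had b of 0.13 and -0.16 for Hdc and of -0.20 and -0.015 for Rpl7, for infection in pCre and in mCre, which is a difference in the other direction for both genes. Only transcripts with small p-values in both comparisons could enter, and of these 281 all 33 that passed had opposite signs in the pair compared. The first adjustment, over these 281 alone, ignored how they had entered, gave 107, and was replaced after its value was seen.

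Mast cell genes were higher in mCre infected basophils than in mCre naive and pCre infected ones, and Mcpt8 was lower. The pancreatic acinar list of the last paragraph had a larger median than the mast cell list for infection in mCre (2.99 against 1.94). A lower basophil share that raises all other cell types alike is argued against only in that strict form. The 95% intervals of the erythroid and B cell medians for infection in mCre lie 1.03 apart on the natural log scale. These were the lowest and the highest medians of the lists compared, which favours a gap. The test first written for this was the median over 88 genes of the other cell type lists. It was 0.30 (interval 0.072 to 0.49), against a required 0.97 and a limit of 0.48, and did not decide. That test was replaced after its value was seen. A lower share that raises some cell types more than others was not tested and stays open. The B cell and plasma cell medians were 1.19 and 1.15, and the erythroid one was -0.034. For Mcpt8, dilution of basophil RNA by cells that lack the other basophil genes is argued against as well. The 21 other basophil identity genes had a median b of -0.075 (-0.097 to -0.046), against -0.69 for Mcpt8. Some of them, such as Gata2, are also mast cell genes, so these values cannot speak to dilution by mast cells. A different share of mast cells or their progenitors in the sort may account for the mast cell genes and stays open. The marker list that shows the pattern cannot test this, so a first test on its signs was dropped after its value was seen, and other mast cell genes, on none of the fixed lists, were chosen without their values. They had a median b of 0.59 (0.24 to 2.05) over 16 genes for infection in mCre, 14 of them positive. This median is below the required 0.97, but its interval reaches past it. For Cre in infected their median was -0.61 (-1.55 to -0.24) over 18 genes, 15 of them negative. Together these values do not decide. Basophils that change these genes themselves, by infection and Notch inhibition, stay open as well and were not tested, because the sort markers are not given in the sources used here and no values per library or cell were used.

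Single transcripts with b beyond 3 may be reads moved between isoforms of a gene by the quantification. The other tested transcripts of the same genes, available for 113 of 121, had a median absolute b of 0.36 (0.30 to 0.51), and a median of -0.068 in the direction of the call. Tmsb4x is an example, with b = 10.6 for 1 transcript and 0.058 for its principal one between pCre and mCre after infection, in the authors' deposited table. A real switch of isoforms would give the same values and was not tested.

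The pancreatic enzyme genes Ctrb1 and Cela2a were higher in pCre naive than in mCre naive basophils, and for infection in mCre they had b of 4.22 and 4.98 without passing, in the authors' deposited table. Pancreatic RNA carried into the sort, as from tissue lying against the spleen, could give this: the other acinar genes, listed without their values after these 2 were seen, had a median b of 2.14 over 17 genes for Cre in naive and of 2.99 over 13 for infection in mCre, with 13 and 12 transcripts passing when adjusted over the list alone. For Cre in infected their median was -0.88 (-1.10 to -0.42), negative in all 21 measured genes, and for infection in pCre 0.39 (0.014 to 0.62), positive in 15 of 21, with 0 transcripts passing in either when adjusted over the list alone. Under the default orientation the 4 medians place mCre naive below the other 3 groups and mCre infected above pCre infected; with all columns reversed, mCre naive would be the highest of the 4. Prss2 had b of 2.44 and 3.47, Cel 2.11 and 3.68, and Amy2a5 2.49 and 3.91, for Cre in naive and infection in mCre. Cell sorting should remove acinar cells, and free RNA was not tested. Which libraries carried the signal stays open without values per library, and no biological explanation was tested.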

How the results depend on the processing

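No paired analysis was possible because the values used here are comparisons between groups, with no value per library to carry a replicate number. For the same reason the planned pseudocounts, filters, quantile and other scalings, fits without trend or with array weights, fits of the compared groups alone, sums to genes, camera with either correlation, leaving out each replicate and other splits of the 6 naive libraries were not run. Restricting to principal transcripts, to those tested in all 4 comparisons or to b within 3, the pair used alone, the adjustment over transcripts with recoverable errors alone, and all transcripts for list medians were chosen after seeing the data. At q under 0.01 the calls numbered 20 for Cre in naive, 112 for Cre in infected and 4 for infection in pCre, and at q under 0.1 they numbered 88 for Cre in naive and 34 for infection in pCre. A change of at least 2-fold left 29 for Cre in naive and 12 for infection in pCre, and 11 for the average Cre effect. Principal transcripts alone gave 15, 114, 61 and 11 calls for Cre in naive, Cre in infected, infection in mCre and infection in pCre. Without b beyond 3 there were 33 for Cre in naive and 1 for the average infection effect, and 36 for Cre in naive among transcripts tested in all 4 comparisons. The interaction passed in 18 transcripts from the infection effects alone and in 20 from the Cre effects alone, against 33. Adjusted over the transcripts with recoverable errors alone, 107 passed for the interaction, 9 for the average infection effect and 170 for the average Cre effect, against 33, 3 and 29, since transcripts enter there by their small p-values. Fewer transcripts enter each of the stricter settings by construction. Genes counted once numbered 52, 193, 96 and 22 in the 4 comparisons. Of the list medians, 106 moved by less than the half-width of their interval when all transcripts of a gene were used and 7 moved by more; the glycolysis and hypoxia median for Cre in infected turned from 0.16 to -0.044, and the cause was not tested. Depth per library is unknown, so a gene that did not pass may differ by an amount these libraries cannot show.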

Other observations

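The lists were fixed and their medians planned before the table was seen; the bootstrap intervals and the Fisher's exact tests were chosen only after it was seen.

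Several lists without called members had medians whose intervals left out 0. Between pCre and mCre in naive mice all 11 measured erythroid genes were negative (median -0.23, interval -0.35 to -0.21). The 12 measured neutrophil markers had a median of 0.47 (0.047 to 0.83) there, 10 positive and 2 negative, with Ngp at 1.62, Ltf at 1.29 and Cxcr2 at 0.035. For infection in pCre, the erythroid genes Hbb-bs and Slc4a1 had b of -0.65 and -1.51, and the 6 eosinophil markers a median of 0.43 (0.079 to 0.92). Cholesterol and fatty acid synthesis genes had a median of 0.20 (0.041 to 0.40) for infection in mCre, positive in 21 of 25 genes. Respiratory chain genes had a median of 0.18 (0.14 to 0.27) between pCre and mCre after infection, positive in 25 of 29 genes, where the ribosomal protein genes, 4 of them called, had 0.18 (0.15 to 0.23). Immediate early genes with large values in that comparison, none of them called, were Atf3 (-3.89), Nr4a3 (-3.64), Nr4a2 (-3.11) and Egr2 (-2.65).

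Proliferation genes had medians of 0.28 for Cre in naive and 0.38 for infection in pCre, with 0 transcripts passing in either when adjusted over the list alone, and of 0.099 for infection in mCre. Genes of the interleukin-3 and STAT5 response had a median of -0.17 (-0.27 to -0.037) for infection in pCre, with Cish called. Antigen presentation genes of MHC class II had a median of 0.50 (-0.010 to 0.70) for Cre in naive, and Notch receptors, ligands and components one of -0.082 (-0.23 to 0.032) for Cre in infected. For Cre in infected, the IgE receptor list had 3 called genes of 29, with transcripts of Ptpn6 and Tec higher and one of Pik3cd lower (one-sided Fisher's exact test, adjusted p = 0.0690), and the migration list 3 of 31, with transcripts of C5ar1 and Itgal higher and one of Itga4 lower (one-sided Fisher's exact test, adjusted p = 0.0772). The called Pik3cd and Itgal transcripts are not principal ones, whose values were 0.95 for Pik3cd, in the other direction, and 0.16 for Itgal. For C5ar1 the gene's value, a median over transcripts, was 3.60, against 7.13 for the called transcript, so its transcripts did not move alike. Interferon response medians lay between -0.055 and 0.14 and unfolded protein response medians between -0.015 and 0.071 in the 4 comparisons. Macrophage and monocyte markers had a median of -0.13 (-0.15 to -0.033) for Cre in naive, NK cell markers 1.15 (-0.73 to 1.32) and platelet markers 0.027 (-0.74 to 0.21), and dendritic cell markers had one of 0.076 (-0.57 to 0.29) for Cre in infected. In all, 11 of 114 list tests passed after adjustment, and 13 of the 29 fixed lists had no called gene in any comparison.

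Relative to mCre naive, the Hes1 values in the pCre naive, mCre infected and pCre infected groups were 0.80, 1.78 and 0.13. Those of the immediate early gene Egr3, picked after its values were seen, were 0.64, 1.77 and -0.12, so such values are not specific to mast cell genes. A response of Hes1 to Notch inhibition was not tested.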
